A study of Caenorhabditis elegans with 90 samples.

How the data were processed

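The samples were early embryos at the 4-cell stage, cut from young adults and collected in lots of 50 per sample, per the labels' protocols. Worms were fed a sporulation-defective Bacillus subtilis strain instead of the usual Escherichia coli food, and the RNA was amplified in successive rounds of in vitro transcription and labelled with Cy3. Group and replicate number came from the sample titles, which gave 6 strains, 5 environments and 3 replicates. What infection and High-pH-Salt consisted of is not given in the sources used here, and the treatment protocol is given only in part. Nothing in the labels says how far back the replicates were separate, so p-values measure the spread between these samples.

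The authors deposited, per array, the spot intensity written by Agilent Feature Extraction 9.5.3.1, per the file headers. The processed intensity is background-subtracted and spatially detrended within an array, per the file headers, with no scaling between arrays. The value table of the series held the same intensity on a linear scale (ratio between 0.995 and 1.005), as deposited, with no scaling or centring between arrays. The array had 15208 gene probes, 1 per gene, and 536 control spots, which were left out.

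From there, the log2 of the processed intensity was taken, spots marked as non-uniform outliers were set as missing (a median of 72 per array), and each array's 75th percentile was subtracted. The 75th percentile lay between 26250 and 49830 and the median signal between 261.9 and 755.0. A probe was kept if it was well above background on all 3 arrays of at least 1 of the 30 groups, which kept 11914 genes. Of these 11912 were tested, because in 2 a group had no value left. Up to 32 gene spots per array were saturated and were kept. The limma test (limma 3.58.1, R 4.3.3, statmod 1.5.0) was fitted to all 90 arrays with 30 group means, with 60 residual degrees of freedom where no spot was missing. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and the threshold was 0.05. Environment contrasts averaged over the 6 strains and strain contrasts over the 5 environments. Interactions were tested with joint tests of 20 contrasts, or of 5 contrasts for each environment. Figures were drawn with matplotlib.

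Where a probe was not well above background on any array of one side, the fold is given as at least a value. It sets the bright side's mean against the mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

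Genes were to be named by a rule fixed before the data were examined, which took the largest changes among genes past the threshold with the same sign in at least 5 of 6 strains or in all 5 environments, and the smallest interaction p. The tables given here do not pair these identifiers with names or positions (0 matched), so the rule was run without its demand for a name. At most 2 genes that rose and 2 that fell are printed per comparison. For the same reason 29 gene lists fixed before the data were examined, among them markers of other tissues, could not be tested. Carry-over of adult tissue, or a difference in stage between groups, therefore could not be checked with them. The length of upstream regions and the position on chromosomes were not analysed here. The sid-1 gene could not be picked out by name, so it may be among the genes given by identifier.

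The headers gave 15 slides and 3 scan days. The replicate number and the scan day were the same division of the arrays, with 30 arrays of all 30 groups on each day, so the block by replicate number is also the block by scan day. Deviations from the group means correlated at 0.206 on average between arrays of the same number and at -0.103 between different numbers. Of the pairs with the same number 84.0% were over 0.1, and the lowest was -0.185. The Control arrays lay unevenly over the 4 position columns of the slides, with 0, 3, 6 and 9 arrays, and those of 25C with 7, 4, 4 and 3. The highest correlation of any 2 arrays was 0.991, with a median signal difference of 13.0%, so no array was taken for a copy of another.

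The fit was checked against limma on the measured values of genes with a value on every array. Recovery of known changes was then measured on simulated arrays. With 200 genes changed among 11912, an environment contrast recovered 43.3%, 83.6% and 97.0% of genes changed by 0.5, 1 and 2 on the log2 scale. A strain contrast recovered 47.8%, 76.1% and 98.5%. The interaction test with 1 group changed recovered 0%, 8.96% and 48.5%, and a response within 1 strain 4.48%, 28.4% and 72.7%. Of the calls, 5.1%, 8.64%, 2.56% and 6.67% were false in these 4 simulations, in that order. The simulated noise was independent between arrays, without effects of scan day or slide. Fewer genes were changed than the environment contrasts called in the measured data, so these percentages do not carry over directly. Alternatives were quantile normalization, other filters, blocks by replicate number and slide, a robust trend, array weights, the deposited value table, only the groups compared, and arrays, replicates, strains or environments left out. Chosen after seeing the data were normexp on the median signals, the array position, outlier spots kept, scan days fitted alone, 1 outlying array left out, responses compared between scan days and the interaction share that the spread within groups would give.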

Results

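RNA from 4-cell embryos of 6 Caenorhabditis elegans strains, each kept in 5 environments, was measured on 90 single-colour arrays. The strains were N2, the standard laboratory strain, the wild strains AB2, CB4856, RC301 and CB4857, and sid-1, labelled by the name of a gene needed for the spread of RNA interference between cells. The environments were labelled Control, 25C, High-pH-Salt, Liquid and infection. The 25C worms were grown at 25 °C and all others at 20 °C. Each of the 30 combinations had 3 arrays, and each array was made from 50 embryos. Between 8040 and 13555 of the 15208 gene probes on an array were well above background (median 10904). The number of arrays limits the precision of every value. A strain contrast had a median standard error (SE) of 0.165 on the log2 scale and an environment contrast one of 0.15. The files do not pair the gene identifiers with gene names, so genes are given by identifier and only a few are printed.

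The first principal component of the 30 group means held 19.9% of their variance and placed CB4856 at one end, between 60.38 and 68.96, and N2 and sid-1 at the other. The second component held 13.9% and placed the Control group above the 25C group in every strain. Of the 11912 genes tested, 5241 differed between strains in a joint test of the 5 strain contrasts, and 7123 differed between environments in a joint test of the 4 environment contrasts. Both tests were passed by 4177 genes and neither by 3725. Over the 9022 genes with a value on every array, the median share of a gene's variance was 10.6% for strain and 14.4% for environment. Arrays with no effect of any kind would give 5.62% and 4.49% on average. Of the variance summed over these genes, strain held 29%, environment 17.1% and their interaction 14.1%. The median share of the interaction was 13.2%, where arrays with no effect of any kind would give 22.5% on average. The spread within groups alone would give a median of 17.2% for it, and 11.3% once the scan day, with a median share of 10.9%, was taken out of that spread.

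**Figure D1:**
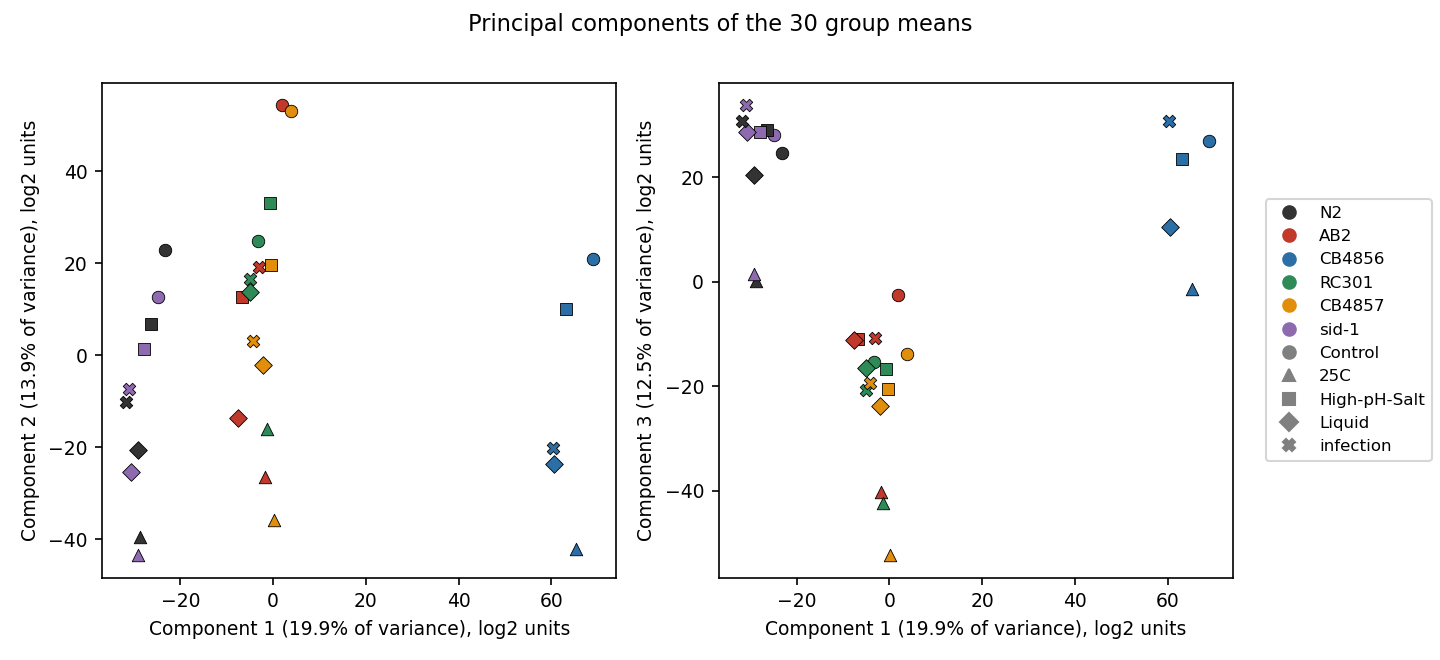
Principal components of the 30 group means over all genes tested, in log2 units, with strain shown by colour and environment by symbol. CB4856 groups lie above 60 on component 1, and in each strain the 25C group has the lowest value on component 2.

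The first question was which genes changed when worms were grown at 25 °C instead of 20 °C. Embryos of 25C worms had 1861 genes higher and 2526 lower than in Control. WBGene00001557 rose by 6.06 on the log2 scale (SE 0.31), from -9.60 ± 1.40 in Control to -3.54 ± 0.47 at 25C (SD, n = 18 each), with an adjusted p of 5.26e-25. It was well above background on 4 of the Control arrays and on all 18 of the 25C arrays, so the size is imprecise. WBGene00018577 rose by 3.47 (SE 0.23, adjusted p 3.32e-20). WBGene00020414 fell by 5.34 (SE 0.63, adjusted p 1.59e-10) and WBGene00015994 fell by 5.30 (SE 0.61, adjusted p 2.32e-10). Both were well above background on 16 Control arrays but on only 6 and 5 of the 25C arrays, so these sizes are imprecise. Their SD over the Control arrays was 2.92 and 2.25. These 4 genes moved in the same direction in all 6 strains, where the rule for printing required at least 5. So did 3095 of the 4387 genes called. Changes of at least 2-fold numbered 381 upward and 880 downward. The share of calls that were higher was 42.4%, and 51.2% after quantile normalization, which gives all arrays the same distribution of intensities. With only genes well above background on all 90 arrays tested, it was 51.1%. Falls outnumbered rises among the dimmest of 3 equal classes of genes, 902 against 295, but not among the brightest, 566 against 652. The excess of falls thus depended on the scaling and on the genes tested. Within the 3 scan days, 1889, 2680 and 3437 genes were called.

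High-pH-Salt embryos had 844 genes higher and 1308 lower than in Control. Most changes were small, as 46 genes rose and 275 fell by at least 2-fold. WBGene00013073 was not well above background on any Control array and was well above it on 16 of the 18 High-pH-Salt arrays. It was at least 1.87-fold higher in High-pH-Salt (adjusted p 1.28e-09). WBGene00015265 rose by 2.08 (SE 0.18, adjusted p 2.56e-13), from -8 ± 1.06 to -5.93 ± 0.74 (SD, n = 18 each). WBGene00020414, which also fell at 25C, fell by 3.34 (SE 0.63, adjusted p 5.29e-05), and WBGene00004965 fell by 3.23 (SE 0.57, adjusted p 1.8e-05), each in 5 of 6 strains. They were well above background on 8 and 6 of the 18 High-pH-Salt arrays, so these sizes are imprecise. Their SD over the Control arrays was 2.92 and 3.26. The share of calls that were higher was 39.2%, 56.3% after quantile normalization and 19.9% with normexp on median signals, which called 3630 genes, so neither the size nor the side with more genes was firm. Without replicate 2 the count was 956 instead of 2152, and within the 3 scan days it was 345, 1371 and 458.

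Liquid culture changed 3111 genes, 1152 higher and 1959 lower. WBGene00009754 rose by 6.21 (SE 0.50, adjusted p 1.65e-15) and WBGene00012175 by 5.94 (SE 0.28, adjusted p 7e-26), from -10.40 ± 0.66 to -4.47 ± 2.24 (SD, n = 18 each). WBGene00012175 was well above background on 1 of the Control arrays and on 17 of the Liquid arrays, so the size of its rise is imprecise. WBGene00000656 fell by 4.64 (SE 0.45, adjusted p 1.08e-12), from -0.33 ± 0.90 to -4.97 ± 1.97, and was well above background on all 18 arrays of both environments. WBGene00004965, which also fell in High-pH-Salt, fell by 4.23 (SE 0.57, adjusted p 1.88e-08), an imprecise size since it was well above background on 2 of the Liquid and 11 of the Control arrays. Changes of at least 2-fold numbered 167 upward and 542 downward. The share of calls that were higher was 37%, and 51.8% after quantile normalization. Within the 3 scan days, 664, 1749 and 2202 genes were called.

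The infection environment had 273 genes higher and 1376 lower than in Control, fewer in all than the other environments, though not without replicate 2, where High-pH-Salt had 956 and infection 1464. The direction depended on brightness, with 11 higher and 612 lower among the dimmest of 3 equal classes, 143 and 697 in the middle one, and among the brightest 67 lower and more than that higher. The mean of the arrays' median signals was 453.3 in infection and 580 in Control. Only 5 of the rises reached 2-fold, against 526 of the falls. WBGene00000443 rose by 1.48 (SE 0.20, adjusted p 2.51e-07) and WBGene00015933 by 1.35 (SE 0.38, adjusted p 0.0104). WBGene00015994, which also fell at 25C, fell by 4.69 (SE 0.59, adjusted p 6.31e-08), and WBGene00003099 fell by 4.47 (SE 0.47, adjusted p 1.34e-09), from -5.11 ± 1.48 (SD, n = 17) to -9.49 ± 2.00 (SD, n = 18). All 4 moved in the same direction in all 6 strains, where the rule for printing required at least 5. The 2 that fell were well above background on only 6 and 7 of the infection arrays. The call of WBGene00015933 ended without replicate 1 (adjusted p 0.0756) and without replicate 2 (adjusted p 0.0993). Quantile normalization gave 603 higher and 589 lower, moved the median of all genes by 0.10 and kept 786 of the 1649 calls in the same direction. With the replicate number as a block 2498 genes were called, and within the 3 scan days 60, 166 and 1480 were.

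**Figure D2:**
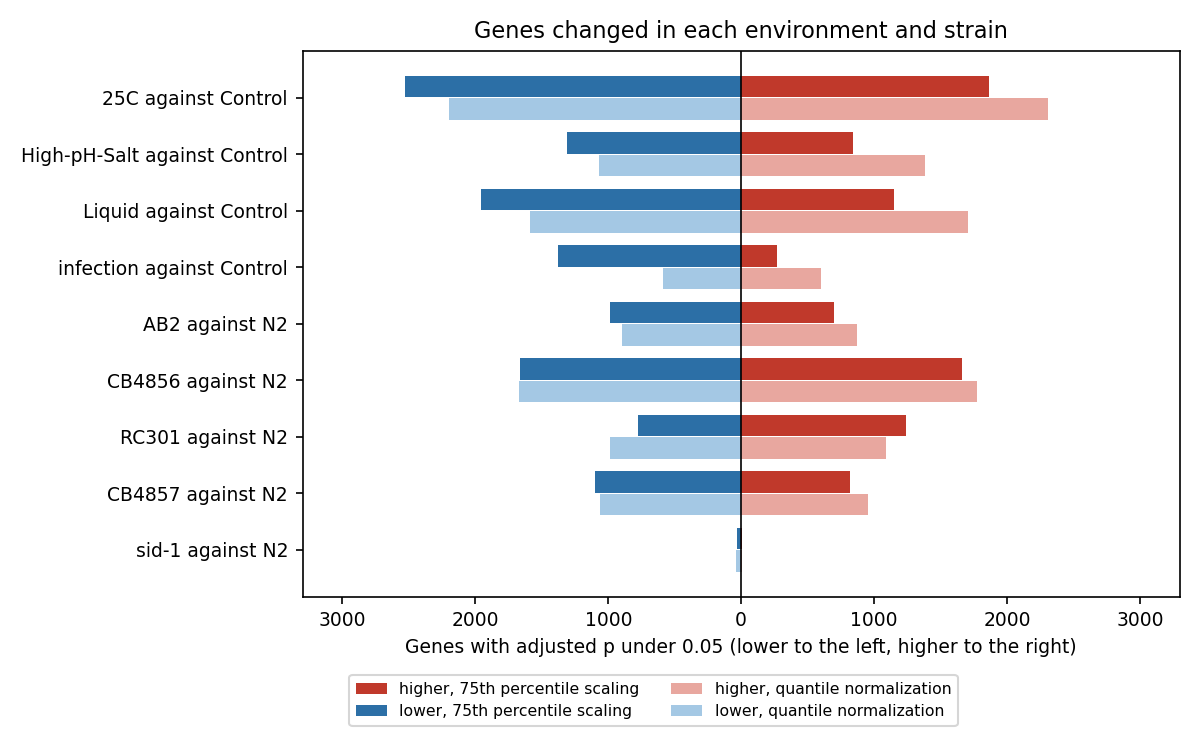
Number of genes with adjusted p under 0.05 in each environment against Control (18 arrays against 18) and each strain against N2 (15 against 15), with lower genes to the left and higher genes to the right of 0. Dark bars show scaling to the 75th percentile and pale bars quantile normalization, under which infection had 603 genes higher and 589 lower.

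The 4 environments moved many of the same genes. In all 4, 264 genes fell and 43 rose, and after quantile normalization 194 fell and 85 rose, while 3097 genes were called in exactly 1 environment. At 800 genes a rise in 1 or more environments stood beside a fall in another. Opposite calls ran from 60 genes for Liquid with infection to 390 for 25C with High-pH-Salt, which shared 266 rises and 576 falls. Liquid and 25C shared 661 rises and 1137 falls, where independent lists would share 180 and 415. Their log2 changes correlated at 0.63 across genes, and simulated groups with no effect, set against the same Control arrays, gave 0.50. For 25C with High-pH-Salt the correlation was 0.47, below the 0.50 of the simulation, and for 25C with infection it was 0.51 against 0.50. The covariance for Liquid and 25C was 0.227, against 0.0248 in the simulation, and over the 6 pairs it exceeded the simulated value by 0.0795 to 0.203. Because the Control arrays were shared, the comparison was repeated with one environment measured in 3 strains and the other in the remaining 3. These disjoint sets gave a correlation of 0.49 for Liquid and 25C and 0.32 for High-pH-Salt and 25C, the highest and lowest of the 6 pairs. The same environment measured in disjoint strains correlated at 0.79 for 25C, 0.61 for High-pH-Salt, 0.70 for Liquid and 0.64 for infection. Genes are not independent replicates, so these correlations carry no p.

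A second question was which genes differed between strains whatever the environment. CB4856 differed most from N2, with 1660 genes higher and 1663 lower. WBGene00001154 was higher in CB4856 by 9.26 (SE 0.40, adjusted p 5.87e-30) and WBGene00012058 by 8.96 (SE 0.26, adjusted p 3.37e-39). In N2 they were well above background on 8 and 13 of the 15 arrays. WBGene00013610 was bright on all 15 N2 arrays, at 1.80 ± 0.15, and not well above background on any CB4856 array, which made it at least 1980-fold lower in CB4856 (adjusted p 9.64e-69). WBGene00015747 fell by 13.4 (SE 0.43, adjusted p 7.59e-37) and was well above background on 3 of the 15 CB4856 arrays. Within the 3 scan days, 1947, 2062 and 1997 genes were called.

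The other wild strains differed from N2 at fewer genes. AB2 had 697 genes higher and 984 lower, RC301 1238 higher and 773 lower, and CB4857 818 higher and 1101 lower. After quantile normalization, which gives all arrays the same distribution of intensities, these were 871 and 894, 1090 and 990, and 957 and 1065. The imbalances were smaller under that scaling. WBGene00015747 fell in each of them too, by 13 in AB2, 13 in RC301 and 13.7 in CB4857 (SE 0.43 each), from 3.01 ± 0.20 in N2 (SD, n = 15). It was well above background on 5, 2 and 1 of their 15 arrays, so these sizes are imprecise. WBGene00019079 was higher in AB2 by 6.26 and in CB4857 by 6.35 (SE 0.11 each), from -6.55 ± 0.40 in N2 to -0.28 ± 0.19 and -0.20 ± 0.24 (SD, n = 15 each). WBGene00010555 was higher in AB2 by 9.06 (SE 0.21, adjusted p 5.19e-45), WBGene00006882 in RC301 by 6.70 (SE 0.28, adjusted p 4.05e-30), and WBGene00007520 in CB4857 by 7.55 (SE 0.20, adjusted p 2.62e-40). WBGene00018239 was higher in RC301 by 6.41 (SE 0.27, adjusted p 4.87e-30) and WBGene00013358 fell by 11.9 (SE 0.16, adjusted p 2.94e-58). The low side of 3 of these was mostly background, with WBGene00006882 well above it on 2 N2 arrays, WBGene00013358 on 3 RC301 arrays and WBGene00017589 on 2 AB2 arrays, so their sizes are imprecise. WBGene00017589 fell by 11.4 in AB2 (SE 0.36, adjusted p 8.2e-37), and in CB4857, where it was not well above background on any array, it was at least 1580-fold lower (adjusted p 2.35e-39). All 4 wild strains were higher than N2 at 209 genes and lower at 230. Of these, 83.3% and 66.5% also differed in the same direction from sid-1 in all 4. Independent lists would share 0.693 and 0.824 genes, but the N2 arrays entered all 4 contrasts. Within single scan days the counts were between 563 and 716 for AB2, 736 and 1168 for RC301, and 889 and 1011 for CB4857.

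The sid-1 strain differed from N2 at few genes, with 10 genes higher and 35 lower. WBGene00004795 fell by 4.86 (SE 0.14, adjusted p 6.38e-38), from -0.97 ± 0.45 to -5.84 ± 0.49 (SD, n = 15 each), and WBGene00001816 fell by 3.50 (SE 0.13, adjusted p 6.4e-32). WBGene00022519 was higher by 1.68 (SE 0.16, adjusted p 1.89e-11) and WBGene00009453 by 1.64 (SE 0.19, adjusted p 4.97e-09). Each of the 4 differed in the same direction in all 5 environments, as the rule for printing required. With the replicate number as a block 109 genes were called, among them all 45, and within single scan days, with fewer arrays, 10, 7 and 6 were. Without replicate 3 of N2 in Control there were 28 calls, and without replicate 2 of N2 in Control 70.

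Among pairs of strains, sid-1 and N2 were the closest and CB4856 and sid-1 the farthest apart, at 3822 genes. AB2 and CB4857 differed at 689 genes, fewer than any other pair apart from N2 and sid-1. CB4856 differed from each of the other strains at 2971 or more genes.

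**Figure D3:**
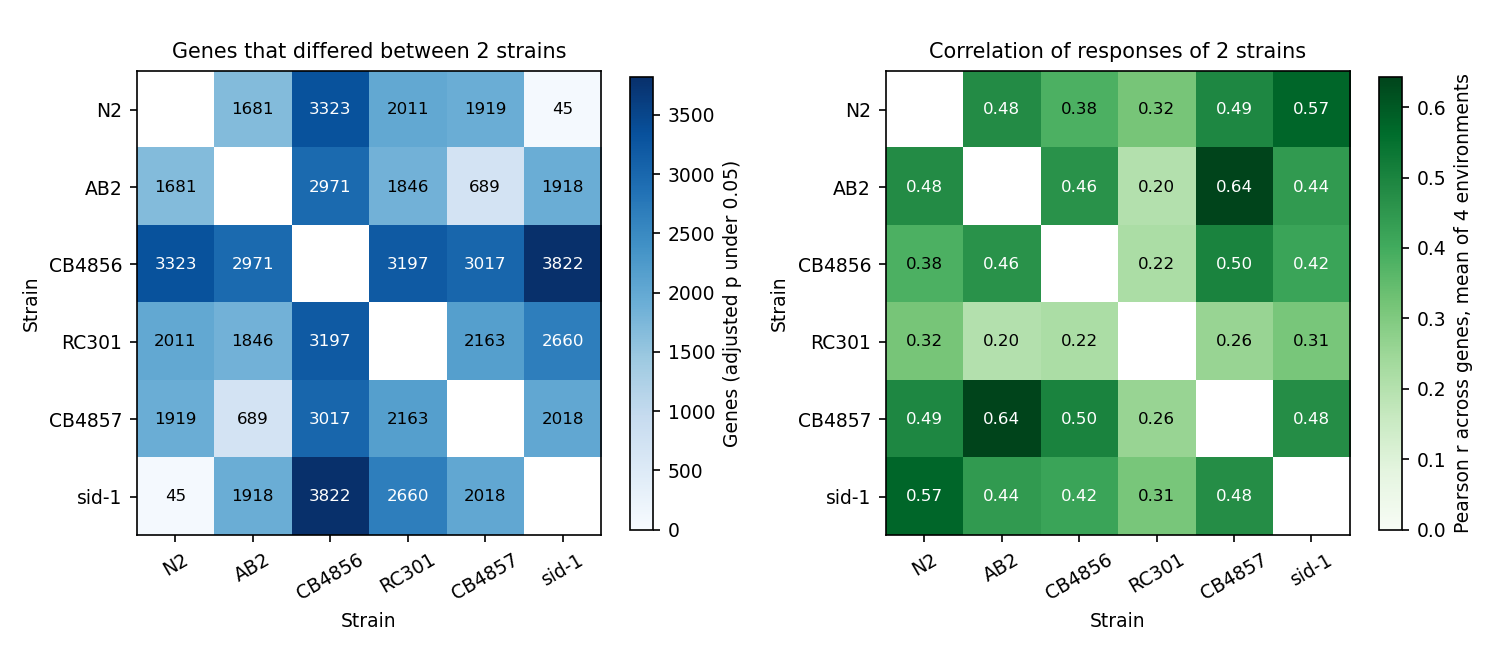
Left, number of genes with adjusted p under 0.05 between each pair of strains (15 arrays each), from 45 for N2 and sid-1 to 3822 for CB4856 and sid-1. Right, Pearson correlation across genes of the log2 changes against Control of each pair of strains, as the mean of 4 environments, which is highest at 0.64 for AB2 and CB4857.

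The series title names interactions of genes and environment, so the third question was at which genes the response depended on the strain. The joint test of 20 interaction contrasts called 497 genes, or 4.17% of those tested. Of these, 474 also differed between environments and 467 between strains. The strains differed in their response to 25C at 343 genes, to Liquid at 164, to infection at 18 and to High-pH-Salt at 5. Single arrays moved these counts, to between 87 and 296 for Liquid and 0 and 32 for High-pH-Salt. Infection rose to 264 without replicate 3 and 145 without replicate 2 of CB4856 in infection. Without its replicate 1, the array with the highest residual SD, the infection count stayed at 18. Set against the mean of the other strains, CB4856 differed in infection at 424, 350 and 19 genes in these fits, in that order. The count for 25C stayed the highest without any single array, and the order of the other 3 did not. Genes of middle brightness made up 375 of the 497, with 93 among the dimmest and 29 among the brightest of 3 equal classes. WBGene00016935 (interaction adjusted p 1.43e-10) fell by 3.17 at 25C in CB4857 (SE 0.18, n = 3 against 3, adjusted p 2.39e-21), from -0.39 to -3.56. In N2, AB2, CB4856 and RC301 it fell by 0.62 to 0.96, and in sid-1 the change was -0.28 (adjusted p 0.55). WBGene00010971 (interaction adjusted p 4.74e-09) rose at 25C by 4.00 in N2, 4.91 in AB2, 4.75 in CB4856, 2.54 in RC301 and 3.54 in sid-1, and fell by 1.76 in CB4857 (SE 0.61 each). WBGene00013336 (interaction adjusted p 4.82e-11) fell by 5.88 at 25C in CB4857 (SE 0.42, adjusted p 3.56e-17), where it was well above background on 1 of 3 arrays, and by 1.97 in RC301 (adjusted p 0.000753). Its change was -0.95 in AB2 (adjusted p 0.154) and 0.20 in N2 (adjusted p 0.924), and in CB4856 it was not well above background at 25C or in Control. WBGene00003630 (interaction adjusted p 3.84e-09) rose by 1.46 at 25C in AB2 and by 0.94 in CB4857, and fell by 1.1 in CB4856 (SE 0.20 each), where it was well above background on 1 of the 3 arrays at 25C, so that fall is imprecise. Opposite calls in 2 strains in the same environment were found for 30 of the 497 genes. With the replicate number as a block 1080 genes were called, with 627 for 25C, 313 for Liquid, 76 for infection and 19 for High-pH-Salt. With 1 of the 3 replicates left out 111 to 140 genes were called. A scan day held 1 array of each group, so no test within a day was possible, and deviations from the sum of strain and environment means on one day correlated with those of the other days at 0.15 to 0.18 (mean over 30 groups).

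**Figure D4:**
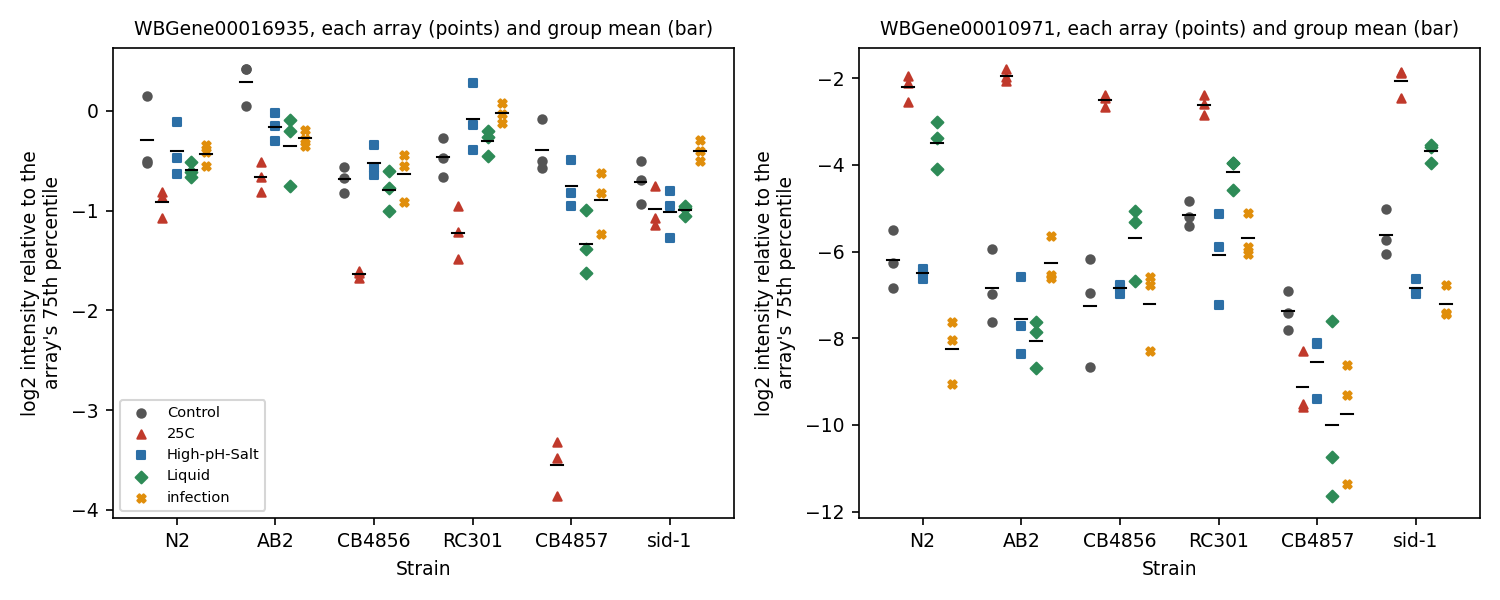
Log2 intensity relative to the array's 75th percentile of WBGene00016935 (left) and WBGene00010971 (right) on each array, with bars at the group means (n = 3) and environments shown by colour and symbol. At 25C both genes were lower in CB4857 than in the other strains, at -3.56 and -9.13.

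Responses within single strains varied widely in size. The number of genes called at 25C ran from 576 in sid-1 to 1863 in CB4857, in High-pH-Salt from 34 in CB4856 to 479 in AB2, and in Liquid from 105 in RC301 to 1052 in AB2. Infection changed 604 genes in CB4856, 295 in CB4857 and 101 in AB2, and 5 in RC301, 6 in sid-1 and 14 in N2. With the replicate number as a block these were 883, 467 and 280, and 19, 10 and 85, in the same order of strains. The 604 rested in part on replicate 1 of CB4856 in infection, which had the highest residual SD of the 90 arrays, at 0.99, and without it 178 genes were called. The median over the 24 pairs was 410, and 761 with the replicate number as a block. A gene called in one strain and not in another is not shown to differ between them, and the test of that difference is the interaction test. Uncorrected for noise, which lowers correlations most where responses are small, the mean correlation over the 4 environments was highest for AB2 and CB4857, at 0.64, and next for N2 and sid-1, at 0.57. The responses of RC301 correlated with those of the other strains at a mean of 0.26, and those of each other strain at 0.40 to 0.47. No array was shared in these correlations across genes. The 4 environments jointly set CB4856 apart from the mean of the other 5 strains at 475 genes, and the other strains at 25 for N2, 95 for AB2, 86 for RC301, 106 for CB4857 and 109 for sid-1. Without replicate 1 of CB4856 in infection the count for CB4856 was 264, and without replicate 3 it was 756. Tested against N2 alone, the response of sid-1 differed at 2 genes.

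**Figure D5:**
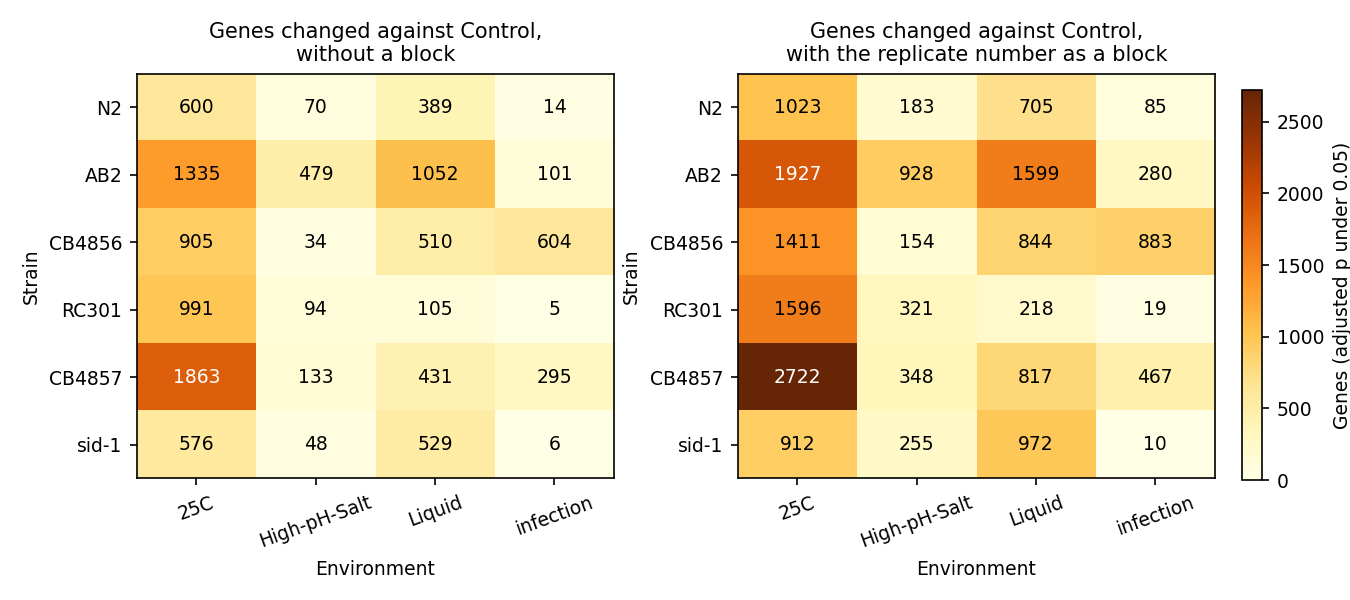
Number of genes with adjusted p under 0.05 in each environment against Control in each strain (3 arrays against 3), without a block (left) and with the replicate number as a block (right). Counts are highest for CB4857 at 25C, at 1863 and 2722.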

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

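The tests of array position and of the noise of RC301, and the fits without single arrays of CB4856 in infection, were chosen only after the result was seen. Each count and gene of the next paragraph was singled out because strains differed in their response to the same environment by a test of the difference itself.

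The joint test of strain by environment called 497 genes, and the tests of each environment called 343 for 25C, 5 for High-pH-Salt, 164 for Liquid and 18 for infection. Leaving out single arrays gave 0 to 32 for High-pH-Salt, 87 to 296 for Liquid and up to 264 for infection. The 264 came without replicate 3 of CB4856 in infection, and without its replicate 1 the infection count was 18. Set against the mean of the other 5 strains, the response over 4 environments differed at 25 genes for N2, 95 for AB2, 475 for CB4856 (264 without its replicate 1 in infection, the array farthest from its group), 86 for RC301, 106 for CB4857 and 109 for sid-1. Among single genes, the adjusted p of the interaction was 4.82e-11 for WBGene00013336, 1.43e-10 for WBGene00016935, 3.84e-09 for WBGene00003630 and 4.74e-09 for WBGene00010971.

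The counts of the 4 environment and 5 strain contrasts, of the joint interaction test and its 4 parts, and the median within strains were set against 100 permutation splits, the real one included. Environment names were permuted within a strain, strain names within an environment, and for the interaction the deviations from the sum of strain and environment means among arrays of the same replicate number. Only the permutation for the interaction kept the replicate number, and with it the scan day. For all 15 of these, 1 of the 100 splits reached the real count, which was the real one itself. In the other splits the real effects entered the spread within groups, which lowers the counts there. They are therefore not splits with a single effect absent and the rest kept. The highest count of any other split was 425, for CB4856 against N2, where 3323 genes were called.

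The first pattern weighed is that the 4 environments shared part of their change from Control. Noise of single Control arrays, shared by the contrasts, was excluded, since disjoint strains, which share no array, still gave a mean correlation of 0.383. The lowest pair of environments had 0.319. A deviation common to the Control arrays of different strains would remain in this comparison and was not tested. Quantile normalization left the mean correlation at 0.37, and with the array position in the model 100% of the mean covariance remained. The Control arrays also had the highest mean of median signals, at 580 against 453.3 to 540.2 in the other environments, and whether signal or RNA quality accounts for part of the pattern was not tested. Other differences of the Control embryos and a common response to the 4 environments stay open too, and the series has no further unstressed group to separate these.

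The second pattern is that the responses of RC301 resembled those of other strains less than theirs resembled each other. Noise could not be excluded as the cause, because a first correction for it gave 1.34 for N2 and sid-1, an impossible correlation. The comparison of different scan days that replaced it gave a gap of 0.155 to the next strain but again 1.36 for N2 and sid-1, so neither decides. Scan days 1 and 2 alone gave no correlation over 1 (highest 0.873) and a gap of 0.0684 to N2. The other pairs of days reached 1.39 and 2.11, so this rests on 1 pair of days. The mean residual SD was 0.51 for RC301 arrays and 0.48 to 0.58 for those of the other strains. A single deviant Control array was excluded, because with each of the 3 left out in turn the gap stayed at 0.112 or more. A response of its own in RC301 remains open beside noise, but the direct test did not single RC301 out, as it called 86 genes for RC301 and more for every other strain apart from N2.

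The third pattern is that changes of at least 4-fold in CB4856 against N2 were mostly falls, at 60.4% (exact 95% interval 55.3% to 65.3%). Quantile normalization, the only other scaling tried here, left 59% (exact interval 54% to 63.9%), so the excess did not rest on the choice between these scalings. The exact intervals treat genes as independent, which they are not, so they do not measure the spread between samples. Sequence differences from N2 under the probes could lower the signal of wild strains, and falls made up 65.5% of such changes in AB2 and 60.7% in CB4857, with exact intervals over 50%, but 55.6% in RC301, with an exact interval of 46.8% to 64.1%, and after quantile normalization 64.2% in RC301, with an exact interval of 55.6% to 72.2%. Lower expression in CB4856 would give the same excess, and the probe sequences were not compared with the genomes of the strains, so this remains open.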

How the results depend on the processing

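Chosen only after the result was seen were normexp on the median signals, the array position with and without the block, the outlier spots kept and the fit without replicate 1 of CB4856 in infection. Of the comparisons of a count with its value under an alternative, 260 stayed within 1.5 times and 83 did not. For single arrays left out, only the lowest and highest value of each count entered. The replicate block and the equal scan day block entered separately, here and in the tallies of genes that follow. The printed genes were not checked with single arrays left out or under the alternatives chosen after the result was seen. Under the other alternatives no printed gene turned its direction. Their changes stayed past the threshold in 509 comparisons and lost it in 2, both of WBGene00015933 in infection, and the printed interaction genes kept it in all 45. With the replicate number as a block, which is also the scan day block, every call of the contrasts and interactions was kept and calls were added, giving 2498 for infection, 109 for sid-1 against N2, 1080 for the interaction, 627, 19, 313 and 76 for its 25C, High-pH-Salt, Liquid and infection parts, and a median of 761 within strains. It moved no other count by over 1.5 times. Each replicate number held 1 array of every group, so for genes with a value on every array the block altered the spread and not the change. That the calls were kept is therefore no separate support for them. With the slide as a random block the counts were 154 for sid-1, 1011 for the interaction, 580, 19, 284 and 69 for its parts, and a median of 657. Array weights gave 1355 for the interaction and 698, 27, 643 and 105 for its parts. Quantile normalization gave 98 for Liquid in the interaction, and no filter 2 for High-pH-Salt. The strict filter tested 7090 genes instead of 11912 and called 2878 for 25C, 816 for infection, 1303 for RC301 against N2, 3 and 95 for High-pH-Salt and Liquid in the interaction, and a median of 259 within strains. Normexp gave 3630 for High-pH-Salt against Control, and 1 and 94 for High-pH-Salt and Liquid in the interaction. With the array position in the model there were 27 for sid-1, and 2 and 85 for High-pH-Salt and Liquid in the interaction. With position and block together there were 903 for the interaction, and 535, 12 and 49 for its 25C, High-pH-Salt and infection parts. With outlier spots kept, High-pH-Salt in the interaction had 2, and without replicate 1 of CB4856 in infection it had 3. The cause was not tested, except that the strict filter tests fewer genes. Leaving out a replicate, an array, a strain or an environment gave 956 to 2297 for High-pH-Salt and 732 to 1775 for infection against Control, 1322 to 2155 for RC301 and 19 to 70 for sid-1 against N2, and 111 to 622 for the interaction. Its parts ran from 92 to 382 for 25C, 0 to 32 for High-pH-Salt, 4 to 296 for Liquid and 7 to 264 for infection, and the median within strains from 114 to 428.5. The fewest calls mostly came from leaving out 1 of 3 replicates in every group, which leaves fewer samples. The highest value for infection, 264, came without replicate 3 of CB4856 in infection, and the value without its replicate 1 was 18. Low signal limits the dimmest genes, whose median residual SD was 0.90 on the log2 scale against 0.22 for the brightest, and 7090 genes were well above background on all 90 arrays. Normexp on mean signals was not run because the columns lack them, and the choice among probes of a gene does not apply with 1 probe per gene. The alternatives for gene lists, upstream length and chromosome position were not run either.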

Other observations

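Each environment was also set against the mean of the other 3 apart from Control, a comparison chosen only after the result was seen. High-pH-Salt then differed at 3742 genes, 2003 higher and 1739 lower. This count cannot be compared with the 2152 against Control, since the mean of 3 environments is more precise than that of Control alone. The 25C embryos differed at 4678 genes, those of infection at 3236 and those of Liquid at 2512. In infection, 40 of these genes were higher and 282 lower by at least 2-fold.

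The differences of the wild strains from N2 were partly shared. Measured in disjoint environments, so that no array was shared, the differences of AB2 and CB4857 from N2 correlated at 0.557 across genes, and those of the other pairs of wild strains at 0.325 to 0.401. The N2 strain itself was common to both sides. The differences of sid-1 from N2 correlated with those of the wild strains at -0.0376 to 0.0183. With itself across environments CB4856 reached 0.816 and sid-1 0.185.

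On all 15 CB4856 arrays, 3 probes were not well above background while they were on every array of the other strains. For N2, AB2, RC301, CB4857 and sid-1 there were 0 such probes. In N2 and sid-1, 1 probe was well above background on all 30 arrays and on none of the others.

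Each of the 497 interaction genes was assigned to the strain whose responses against Control lay farthest from the mean response of the other strains. This was CB4856 for 123 genes, CB4857 for 94, RC301 for 93, AB2 for 87, sid-1 for 58 and N2 for 42. At 25C and in Liquid, 62 genes were called in both of the tests for single environments.

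Replicate 1 of CB4856 in infection had a residual SD of 0.99, the highest of the 90 arrays, and a median signal of 261.9, the lowest. The mean of the median signals was 580 in Control and 453.3 in infection.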
